A study of Mus musculus with 16 samples.

How the data were processed

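RNA-seq libraries from quadriceps muscle were compared between wild-type and HDAC3 knockout mice, 3 libraries per genotype at rest and 3 per genotype after treadmill running. The authors deposited 2 tables of gene values, 1 per condition, each with FPKM per library, group means, p-values and q-values; which table held rest and which exercise was taken from the tables' own names. Reads were processed with TopHat2, Bowtie, Cuffdiff and HOMER against mm9, per the submitters' processing notes; versions, the Cuffdiff normalization and dispersion settings, the annotation, strandedness and read filters were not given in the sources used here. FPKM values were deposited by the authors as normalized to transcript length and library size, and no counts were used. The p-value and q-value columns were the authors' own Cuffdiff comparison of the genotypes; the tables held no test statistic, fold change or test status. The 4 GRO-seq libraries of the series were not analysed here.

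All 12 library columns were matched to samples by genotype, condition and replicate number, and no per-sample column was left unmatched. The group mean columns equalled the means of the library columns to within 3.3e-06 FPKM. Each table held 24354 rows. A spreadsheet had turned 27 gene names into dates in the values after exercise. No such gene was called, and they were left out. Rows with a p under 1 were taken as tested by the authors (9204 at rest, 9051 after exercise and 9037 of those with a usable name), because the deposited q-values matched a Benjamini-Hochberg adjustment over these rows to within 0.00011. The smallest p in the authors' deposited table was 5e-05 in each condition, and the smallest q was 0.00119 at rest and 0.00132 after exercise, so genes at this floor cannot be ranked by p. Each tested gene had at least 1.94 FPKM in the higher group.

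Depth was unknown. Low values were checked for steps of whole reads in small RNA genes, but over 7 library pairs the log2 ratios of such genes had a median interquartile range of 0.79, so neither whole reads nor relative depths were recovered, and no counting error is given. Pearson correlations of log2 FPKM lay between 0.964 and 0.982 within groups and between 0.96 and 0.975 between genotypes. No pair of libraries shared more than 1 identical value among the 8946 genes at 1 FPKM or more in all 12 libraries, so each library was counted once. Gene names and neighbours were looked up in a reference gene table of assembly GRCm38.p6, which differs from mm9, so no coordinates are given; 9187 of the tested genes at rest and 9020 after exercise were found there.

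The main count per table was the number of genes with a q at or under 0.05 in the authors' deposited table, with direction from the group means. That design was fixed before the data were examined, on the assumption that only pooled values would be given. The tables turned out to hold library values, so a test between libraries was added after seeing the data: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) of the genes the authors tested, with moderated variances and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment. Genes are said to have risen or fallen only when they passed both tests in the same direction; others are given as values. limma differences and SEs are on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1 and was not used.

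Before the data were examined, 31 gene lists were fixed, covering HDAC3 partners, exercise and stress responses, metabolism, fibre types and markers of other cell types. For lists with at least 5 tested members (27 in each table), cameraPR of limma was run on log2((knockout mean + 1)/(wild-type mean + 1)) with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists; the planned statistic was absent from the tables, and this ratio was the stated replacement. camera on library values, with the preset and with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance, were added after seeing the data. Members called when adjusted over the list alone used the authors' p. The knockout effects at rest and after exercise were compared by correlation across genes, by the overlap of calls with Fisher's exact test, and by a limma interaction contrast over the 12 libraries; that contrast was also added after seeing the data, since the planned one needed the absent statistic. A second contrast, with standard errors implied by the deposited p in place of the absent statistic, was run beside it.

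Genes were named by a rule fixed beforehand: Hdac3; the 10 called genes with the largest higher and the 10 with the largest lower log2 ratio, with at least 1 FPKM in the higher group and 0.1 FPKM in both, without predicted or unnamed loci; up to 4 called members per list of lowest q, or the 2 members of highest FPKM where under 2 were called; and, across tables, the 5 leading genes called in each shared direction, up to 5 called in opposite directions and 5 per direction with the lowest p of the difference. Ties of q within a list were to be ordered by the absolute test statistic, which was absent. The absolute limma log2 difference over its SE was used instead, and limma was added after seeing the data. The text gives part of the genes so chosen. A few results were not reported here.

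Alternatives covered other q thresholds, a minimum fold, repeated adjustment, recentring, removal of overlapping genes, other list settings, limma pseudocounts, filters and normalizations, the replicate number as a block, and leaving out each library. Simulated libraries held independent normal values around the mean and spread of each gene, so sets of genes that move together in a library were not imitated. On these, limma recovered 67% of genes changed 2-fold and 98% of those changed 4-fold at rest (9204 genes, 8 false calls). After exercise it recovered 79% and 96% (9037 genes, 11 false calls). The interaction contrast recovered 92% of 200 genes with a 4-fold difference of effects (8854 genes). For the list test, independent normal values were drawn and the largest list, of 71 oxidative phosphorylation genes, was shifted by 1 SD. It was recovered in both tables, which says little about smaller lists or lists whose genes move together. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.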

Results

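RNA was sequenced from quadriceps muscle of male C57BL/6 mice aged 4 months. The mice were wild type or knockout for HDAC3, a histone deacetylase that acts within the NCoR and SMRT corepressor complexes. Muscle was sampled at rest or after treadmill running. Running consisted of 3 bouts of 1 h at 10 m/min with rests of 1 h, and muscle was taken 2 h after the third bout. Each of the 4 groups held 3 libraries, and values were given as FPKM, which scale fragments by transcript length and library size. The resting and the exercised libraries stood in separate tables, so the genotypes were compared within rest and within exercise. FPKM per library summed to between 454359 and 522584, and between 10123 and 10544 genes reached 1 FPKM. Read depth was unknown, so the spread between the 3 libraries of a group was the only measure of error. The labels did not say that libraries came from separate animals. The p-values of limma, camera and fry drew on the spread between these samples, which can be technical. Those of cameraPR and Fisher's exact test compared genes with other genes and did not measure the spread between samples. Values with ± are means and SDs over 3 libraries (n = 3).

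The targeted gene separated the genotypes in every library, although its transcript remained in the knockout libraries. At rest Hdac3 stood at 33.3, 31 and 23.7 FPKM in the wild-type libraries and at 5.51, 6.29 and 8.16 FPKM in the knockout libraries. After exercise the wild-type libraries held 31, 32.0 and 27.6 FPKM and the knockout libraries 5.32, 6.37 and 4.13 FPKM. Hdac3 fell from 29.3 ± 4.99 to 6.65 ± 1.36 FPKM at rest (log2 difference -1.99, SE 0.17, limma adjusted p = 0.00487). It fell from 30.2 ± 2.30 to 5.27 ± 1.12 FPKM after exercise (log2 difference -2.33, SE 0.15, limma adjusted p = 0.00111). In each table it passed limma in all 6 fits with 1 library left out.

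**Figure D1:**
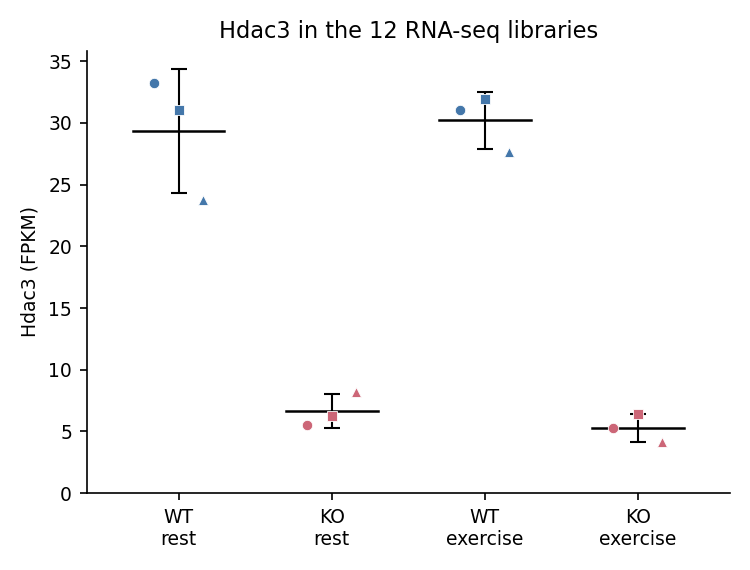
Hdac3 in FPKM in each library, wild type (blue) and HDAC3 knockout (red), at rest and after exercise. Points are libraries, bars are means and error bars are SDs (n = 3); knockout libraries lie at or below 8.16 FPKM and wild-type libraries at or above 23.7 FPKM.

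The resting comparison asked how muscle transcripts differed between the genotypes when the mice had not run. Mthfd2, a mitochondrial enzyme of folate metabolism, rose from 1.80 ± 0.479 to 37.5 ± 12.2 FPKM (log2 difference 3.74, SE 0.26, limma adjusted p = 0.00209). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 1.17 ± 0.360 to 13.3 ± 3.84 FPKM (log2 difference 2.70, SE 0.21, limma adjusted p = 0.00441). Slc7a5, a transporter of large neutral amino acids, rose from 0.341 ± 0.0591 to 2.95 ± 0.729 FPKM. Gamt, which makes creatine, fell from 5.49 ± 0.913 to 0.807 ± 1.13 FPKM (log2 difference -2.01, SE 0.39, limma adjusted p = 0.0333). Actr3b, an actin-related protein, fell from 8.15 ± 1.31 to 1.28 ± 0.562 FPKM (log2 difference -2.03, SE 0.22, limma adjusted p = 0.00789).

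Other leading genes at rest had varied functions. Tlcd2 rose from 0.879 ± 0.409 to 9.36 ± 2.43 FPKM. Mybph, a myosin-binding protein, rose from 4.92 ± 4.61 to 42.1 ± 28.2 FPKM. The growth factor carrier Fgfbp1 rose from 2.45 ± 1.64 to 14.9 ± 5.10 FPKM. The secreted protein Dkk3 fell from 4.27 ± 1.22 to 0.694 ± 0.397 FPKM, and the solute carrier Slc15a5 fell from 6.85 ± 2.29 to 1.32 ± 0.350 FPKM. Map3k7cl fell from 5.96 ± 2.04 to 1.19 ± 0.380 FPKM, and the potassium channel Kcnq5 fell from 3.74 ± 0.295 to 0.821 ± 0.403 FPKM. Srrm4os measured 0.234 ± 0.0770 FPKM in wild type and 10.4 ± 2.56 FPKM in knockout (limma adjusted p = 0.000718). It lies antisense to Srrm4 and strand was not given in the sources used here, so its reads cannot be separated from those of Srrm4. Srrm4os, Mthfd2, Cdkn1a and Tlcd2 passed limma in all 6 fits with 1 library left out. Each of the others missed 0.05 in at least 1 of them, and its highest adjusted p follows. Without wild-type library 2 limma gave an adjusted p of 0.128 for Mybph, 0.116 for Gamt, 0.0863 for Fgfbp1, 0.0816 for Map3k7cl and 0.0746 for Kcnq5. limma fitted without wild-type library 2 gave an adjusted p of 0.0741 for Slc15a5, 0.0556 for Slc7a5 and 0.0536 for Actr3b. Leaving out knockout library 3 gave a limma adjusted p of 0.064 for Dkk3.

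Several large resting differences were called by the authors and did not pass limma on the libraries. Fos measured 2.20 ± 1.17 FPKM in wild type and 21.3 ± 21.9 FPKM in knockout (limma adjusted p = 0.0762), with 46.5 FPKM in knockout library 3. The adenosine receptor Adora1 measured 0.729 ± 0.728 against 6.42 ± 4.93 FPKM (limma adjusted p = 0.0563). Arrdc2 measured 6.79 ± 5.0 against 33.3 ± 29.9 FPKM (limma adjusted p = 0.55). Cardiac actin, Actc1, measured 131 ± 140.3 FPKM in wild type and 14.2 ± 5.87 FPKM in knockout (limma adjusted p = 0.0894). The neutrophil gene S100a8 measured 81.9 ± 137 against 2.5 ± 0.307 FPKM, with 239.5 FPKM in wild-type library 2. Its partner S100a9 measured 76.7 ± 126 against 2.24 ± 2.15 FPKM, with 222 FPKM in that library.

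At rest the authors called 998 of 9204 tested genes, 543 higher and 455 lower in the knockout (q at or under 0.05 in the authors' deposited table). The libraries of the genotypes did not overlap for 82.8% of the called genes and 21.3% of the genes not called, where chance gives 10%. limma on log2(FPKM + 1) of the 6 libraries called 434 genes, 280 higher and 154 lower. Both tests called 393 genes, 252 higher and 141 lower. The limma count was 20 without wild-type library 2, 54 without knockout library 3 and 82 without knockout library 1. It was 195 without knockout library 2 and 269 without wild-type library 1. In every such fit 19 genes passed, and genes are said to have risen or fallen only where both tests on all libraries passed.

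Genes of the unfolded protein and integrated stress response were higher at rest. In this list 9 of 15 tested members were called higher, 0 lower and 6 neither (9 higher and 0 lower adjusted over the list alone). The list passed its test (cameraPR adjusted p = 7.39e-16, adjusted p = 0.573 with an estimated correlation). Both tests passed 6 members, Mthfd2 among them. The transcription factor Atf5 rose from 10.5 ± 1.87 to 29.1 ± 1.41 FPKM (limma adjusted p = 0.00554). Atf4 rose from 136 ± 9.46 to 229.9 ± 30.0 FPKM (limma adjusted p = 0.02). Herpud1, which takes part in degradation at the endoplasmic reticulum, rose from 66.4 ± 1.29 to 105 ± 3.62 FPKM (limma adjusted p = 0.0148). The list median log2 ratio to the wild-type mean was 0.97, 0.65 and 0.69 in the 3 knockout libraries. Atf5 passed every fit with 1 library left out. Without wild-type library 2 limma gave an adjusted p of 0.0954 for Atf4 and 0.0746 for Herpud1.

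The muscle atrophy and autophagy list was also higher at rest. In it 8 of 19 tested members were called higher, 0 lower and 11 neither (9 higher and 2 lower adjusted over the list alone), and 3 passed both tests. The list passed its test (cameraPR adjusted p = 0.000105, adjusted p = 0.573 with an estimated correlation). Cdkn1a rose as above, and the lysosomal protease Ctsl rose from 30.8 ± 5.85 to 71.6 ± 8.73 FPKM (limma adjusted p = 0.0148). The ubiquitin ligase Trim63 measured 116 ± 17.8 against 201 ± 40.9 FPKM (limma adjusted p = 0.0548). limma fitted without wild-type library 2 gave an adjusted p of 0.0743 for Ctsl.

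The lists of fatty acid and amino acid breakdown leaned upward at rest, although most members were not called. In fatty acid uptake and oxidation 6 of 29 tested members were called higher, 1 lower and 22 neither (9 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.0275, adjusted p = 0.688 with an estimated correlation). Of the beta-oxidation enzymes, Echs1 rose from 74.8 ± 3.08 to 151 ± 29.2 FPKM and Hadha rose from 98.3 ± 10.1 to 139 ± 5.84 FPKM. Acads measured 23.8 ± 10.6 against 13.5 ± 2.84 FPKM. In branched-chain and other amino acid catabolism 6 of 30 tested members were called higher, 1 lower and 23 neither (7 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.046, adjusted p = 0.77 with an estimated correlation), and 5 passed both tests. Pcca, of propionyl-CoA breakdown, rose from 11.4 ± 1.04 to 21.1 ± 2.19 FPKM. Ivd, of leucine breakdown, rose from 44.1 ± 1.92 to 78.4 ± 11.4 FPKM, and Dbt rose from 10.3 ± 1.38 to 20.2 ± 3.50 FPKM. Glutamine synthetase, Glul, a member of that list that makes an amino acid and does not break it down, rose from 123 ± 50.3 to 343 ± 116 FPKM. The fatty acid list lost its call without wild-type library 3 (cameraPR adjusted p = 0.202), knockout library 2 (0.0744) or knockout library 3 (0.0942). The amino acid list lost its call without wild-type library 2 (cameraPR adjusted p = 0.084), wild-type library 3 (0.169), knockout library 2 (0.27) or knockout library 3 (0.0836). Leaving out wild-type library 2 gave a limma adjusted p of 0.167 for Glul, 0.0967 for Dbt, 0.0848 for Ivd and 0.0746 for Echs1. Without knockout library 3 limma gave an adjusted p of 0.16 for Hadha and 0.0696 for Pcca.

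Immediate early genes, which respond within minutes to stimuli, were higher at rest in the authors' table. In this list 8 of 18 tested members were called higher, 0 lower and 10 neither (8 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 8.79e-08, adjusted p = 0.77 with an estimated correlation). limma called 0 of its members (6 at an unadjusted p under 0.05), and the list medians in the knockout libraries were 0.30, 0.01 and 0.87 on the log2 scale. Btg2 measured 5.55 ± 0.509 against 11.9 ± 4.86 FPKM (limma adjusted p = 0.077). Cyr61 measured 13.6 ± 7.36 against 35.8 ± 11.6 FPKM (limma adjusted p = 0.0848). Ier5 measured 3.71 ± 0.206 against 6.82 ± 2.51 FPKM (limma adjusted p = 0.116).

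Fibroblast and extracellular matrix markers were lower at rest. Here 0 of 13 tested members were called higher, 5 lower and 8 neither (0 higher and 8 lower adjusted over the list alone, cameraPR adjusted p = 0.00177, adjusted p = 0.645 with an estimated correlation). The matrix protein Thbs4 fell from 33.4 ± 2.21 to 18.1 ± 2.64 FPKM (limma adjusted p = 0.0162). The collagen genes Col1a1 and Col1a2 measured 45.7 ± 18.4 against 26 ± 13.7 FPKM and 77.3 ± 8.66 against 49.9 ± 18.9 FPKM. The list had its lowest library median, -0.75, in knockout library 3 and lost its call without that library (cameraPR adjusted p = 0.165). Immune cell markers were lower at rest, with S100a8 and S100a9 as the called members. Of these markers 0 of 14 tested members were called higher, 2 lower and 12 neither (0 higher and 2 lower adjusted over the list alone, cameraPR adjusted p = 1.59e-10, adjusted p = 0.775 with an estimated correlation). The immune list was not called without wild-type library 2 (cameraPR adjusted p = 0.396). limma fitted without wild-type library 2 gave an adjusted p of 0.0787 for Thbs4.

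Oxidant defence and lipid synthesis lists missed the threshold at rest, although single members passed both tests. Oxidant defence had 4 higher and 1 lower of 15 (7 and 2 adjusted over the list alone, cameraPR adjusted p = 0.0519). The quinone reductase Nqo1 rose from 16.5 ± 1.99 to 43.7 ± 5.06 FPKM (limma adjusted p = 0.00554) and passed every fit with 1 library left out. Catalase, Cat, rose from 46.7 ± 6.4 to 82.3 ± 4.10 FPKM, and Srxn1 rose from 16.2 ± 2.28 to 39.6 ± 13.7 FPKM. Prdx5 measured 104 ± 29.0 against 58.4 ± 10.7 FPKM. Fatty acid and triglyceride synthesis had 5 higher and 1 lower of 17 (5 and 1 adjusted over the list alone, cameraPR adjusted p = 0.0519). Dgat2, which completes triglyceride synthesis, rose from 12 ± 0.764 to 33.0 ± 6.60 FPKM. The malic enzyme Me1 rose from 47.9 ± 3.06 to 71.8 ± 4.75 FPKM, and Thrsp rose from 9.16 ± 0.916 to 20.6 ± 6.55 FPKM. The oxidant list passed without wild-type library 2 (cameraPR adjusted p = 0.0296) and the synthesis list without wild-type library 3 (0.0384). Leaving out wild-type library 2 gave a limma adjusted p of 0.0787 for Cat, 0.0587 for Dgat2, 0.0932 for Me1 and 0.165 for Thrsp. Without knockout library 3 limma gave an adjusted p of 0.105 for Srxn1.

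Genes of fuel use, signalling and the clock moved singly at rest. Glycolysis and glycogen had 4 higher and 1 lower of 24 (5 and 1 adjusted over the list alone, cameraPR adjusted p = 0.232). The glycogen branching enzyme Gbe1 rose from 54.7 ± 5.62 to 97.1 ± 18.4 FPKM, and the muscle fructose bisphosphatase Fbp2 fell from 31 ± 7.24 to 14.7 ± 3.55 FPKM. The tricarboxylic acid cycle list had 2 higher and 1 lower of 28 (3 and 1 adjusted over the list alone, cameraPR adjusted p = 0.739). Idh2 rose from 84.4 ± 14.8 to 195 ± 26.6 FPKM. Pdk1, which inhibits pyruvate dehydrogenase, fell from 24.7 ± 1.07 to 15.8 ± 0.283 FPKM. In the purine list, with 1 higher and 2 lower of 20 (3 and 2 adjusted over the list alone, cameraPR adjusted p = 0.792), the AMP deaminase Ampd3 rose from 2.07 ± 0.539 to 5.49 ± 0.678 FPKM. Insulin signalling had 5 higher and 1 lower of 16 (6 and 1 adjusted over the list alone, cameraPR adjusted p = 0.274). Grb14, which binds the insulin receptor, fell from 13.7 ± 2.59 to 4.84 ± 1.71 FPKM, and Tbc1d4, which regulates glucose transporter traffic, rose from 3.97 ± 2.07 to 11.3 ± 2.56 FPKM. Circadian genes had 4 higher and 1 lower of 18 (6 and 2 adjusted over the list alone, cameraPR adjusted p = 0.212), and the clock factors Arntl and Nfil3 rose from 5.21 ± 0.910 to 11.8 ± 1.70 FPKM and from 14.2 ± 1.87 to 27.4 ± 5.77 FPKM. Polyamine metabolism had 2 higher and 2 lower of 10 (2 and 3 adjusted over the list alone, cameraPR adjusted p = 0.592). Spermine oxidase, Smox, fell from 88.2 ± 17.9 to 41.9 ± 8.88 FPKM, and the antizyme Oaz2 rose from 84.6 ± 4.17 to 126 ± 12.8 FPKM. limma fitted without wild-type library 2 gave an adjusted p of 0.145 for Tbc1d4, 0.138 for Oaz2, 0.122 for Smox, 0.108 for Grb14 and 0.0746 for Pdk1. Leaving out wild-type library 2 gave a limma adjusted p of 0.0678 for Idh2. Without knockout library 3 limma gave an adjusted p of 0.125 for Gbe1, 0.121 for Fbp2, 0.0859 for Nfil3, 0.0774 for Ampd3 and 0.0607 for Arntl.

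Contractile, junction and complex genes at rest gave calls in both directions. Slow fibre genes had 2 higher and 1 lower of 10 (3 and 1 adjusted over the list alone, cameraPR adjusted p = 0.0519), with Csrp3 at 95.3 ± 16.5 against 309 ± 205 FPKM. The slow list passed without wild-type library 1 (cameraPR adjusted p = 0.0106) or knockout library 1 (0.00475). Fast fibre genes had 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone, cameraPR adjusted p = 0.275). The fast light chain Myl1 measured 12893 ± 1509 against 8242 ± 950.0 FPKM (limma adjusted p = 0.0563). Denervation and junction genes had 3 higher and 3 lower of 12 (4 and 3 adjusted over the list alone, cameraPR adjusted p = 0.592). The junction kinase Musk fell from 6.50 ± 0.578 to 3.29 ± 0.634 FPKM, and the acetylcholine receptor subunit Chrnb1 fell from 13.5 ± 2.24 to 7.64 ± 0.654 FPKM. The HDAC3 corepressor complex had 2 higher and 1 lower of 6 (2 and 2 adjusted over the list alone, cameraPR adjusted p = 0.664). The member the authors called lower was Hdac3 itself, the targeted gene. The complex subunits Tbl1xr1 and Tbl1x rose from 10.5 ± 0.449 to 18.2 ± 2.55 FPKM and from 6.20 ± 0.609 to 9.92 ± 0.409 FPKM. Heat shock genes had 1 higher and 3 lower of 14 (1 and 3 adjusted over the list alone, cameraPR adjusted p = 0.792), and Hspb7 rose from 71.0 ± 17.0 to 232 ± 97.2 FPKM. limma fitted without wild-type library 2 gave an adjusted p of 0.124 for Chrnb1, 0.0982 for Tbl1xr1, 0.0932 for Musk and 0.107 for Hspb7. Leaving out knockout library 3 gave a limma adjusted p of 0.103 for Tbl1x.

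Further lists at rest held few calls. Other histone deacetylases had 0 higher and 0 lower of 8 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.948), with Hdac2 at 26.2 ± 2.42 against 22.3 ± 1.02 FPKM. Oxidative phosphorylation had 0 higher and 2 lower of 71 (0 and 1 adjusted over the list alone, cameraPR adjusted p = 0.948), with Ndufs7 at 205 ± 104 against 132 ± 29.9 FPKM. Sterol synthesis had 0 higher and 1 lower of 11 (0 and 1 adjusted over the list alone, cameraPR adjusted p = 0.275). Exercise-responsive metabolic genes had 3 higher and 3 lower of 16 (7 and 3 adjusted over the list alone, cameraPR adjusted p = 0.36), with Pfkfb3 at 13.3 ± 4.33 against 5.01 ± 3.95 FPKM. Medians above 0 stood beside tests in the down direction for 4 lists. These were the corepressor (median 0.17, mean -0.12), denervation (median 0.05, mean -0.10) and polyamine lists (median 0.17, mean -0.11), and oxidative phosphorylation (median 0.01, mean -0.0008). The corepressor list includes the targeted gene Hdac3, whose own fall lowered the mean of that list.

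Markers of other cell types showed few calls at rest. Adipocyte markers had 0 higher and 0 lower of 7 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.849), with Fabp4 at 402 ± 87.6 against 372 ± 49.4 FPKM. Endothelial markers had 0 higher and 0 lower of 10 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.739), with Pecam1 at 24.1 ± 2.85 against 25.8 ± 1.69 FPKM. Smooth muscle and pericyte markers had 0 higher and 0 lower of 5 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.774), with Rgs5 at 166 ± 34.9 against 166 ± 7.16 FPKM. Under 5 blood, Schwann cell or satellite cell markers were tested, so these had no list test. Blood markers had 0 higher and 0 lower of 3 (0 and 0 adjusted over the list alone), and the haemoglobin gene Hbb-b1, which has near-identical copies, measured 124 ± 98.4 against 128 ± 75.8 FPKM. Schwann cell markers had 0 higher and 0 lower of 4 (0 and 0 adjusted over the list alone), with Pmp22 at 16.6 ± 3.90 against 14.5 ± 0.853 FPKM. Satellite cell markers had 0 higher and 1 lower of 4 (0 and 3 adjusted over the list alone), with Cdh15 at 3.45 ± 1.19 against 1.72 ± 0.422 FPKM. No mitochondrially encoded gene was tested in either table. cameraPR called 7 of 27 resting lists, and camera on library values with the preset correlation called 4. fry called 0 (8 at an unadjusted p under 0.05), and camera with an estimated correlation called 0 (1 at an unadjusted p under 0.05). Without knockout library 3 cameraPR called 4.

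The second comparison asked how the genotypes differed after running. Mthfd2 rose from 2.39 ± 0.406 to 36.9 ± 4.09 FPKM (log2 difference 3.48, SE 0.14, limma adjusted p = 6.35e-05). Psat1, an enzyme of serine synthesis, rose from 0.366 ± 0.157 to 3.49 ± 0.587 FPKM (log2 difference 1.72, SE 0.18, limma adjusted p = 0.00483). Gamt fell from 9.28 ± 2.32 to 1.12 ± 0.541 FPKM (log2 difference -2.28, SE 0.23, limma adjusted p = 0.00477). The potassium channel Kcnf1 fell from 2.27 ± 0.217 to 0.189 ± 0.150 FPKM (log2 difference -1.46, SE 0.18, limma adjusted p = 0.0104). The imprinted noncoding RNA Rian fell from 13.8 ± 6.99 to 1.73 ± 0.465 FPKM (log2 difference -2.36, SE 0.30, limma adjusted p = 0.0112).

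Further leading genes after exercise overlapped with those at rest. Tlcd2 rose from 1.5 ± 0.320 to 6.69 ± 1.04 FPKM, and Slc7a5 rose from 0.387 ± 0.267 to 2.93 ± 0.800 FPKM. Mybph rose from 11.6 ± 6.21 to 52.5 ± 8.83 FPKM. Igfals, which binds circulating growth factor complexes, rose from 1.09 ± 0.168 to 4.87 ± 1.67 FPKM. The macrophage gene Cd68 rose from 0.888 ± 0.545 to 4.26 ± 1.45 FPKM. Actr3b fell from 11 ± 1.46 to 2.74 ± 0.856 FPKM, and cardiac actin, Actc1, fell from 237 ± 144 to 20.7 ± 9.34 FPKM. Fam19a5 fell from 2.18 ± 0.863 to 0.377 ± 0.0850 FPKM. Srrm4os, not separable from Srrm4, measured 0.313 ± 0.0949 FPKM in wild type and 8.92 ± 1.74 FPKM in knockout (limma adjusted p = 0.00063). Mthfd2, Psat1, Tlcd2, Gamt, Kcnf1, Rian, Actr3b and Srrm4os passed limma in all 6 fits with 1 library left out. For the others the highest adjusted p in such a fit follows. Without wild-type library 2 limma gave an adjusted p of 0.109 for Cd68, 0.062 for Igfals and 0.0602 for Slc7a5. limma fitted without knockout library 2 gave an adjusted p of 0.0961 for Actc1 and 0.124 for Fam19a5. Leaving out knockout library 1 gave a limma adjusted p of 0.0694 for Mybph.

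Other large differences after exercise did not pass limma, and most of these came with single high libraries. The chaperone gene Dnajb1 measured 28.8 ± 45.1 FPKM in wild type and 2.39 ± 0.183 FPKM in knockout (limma adjusted p = 0.435), with 80.9 FPKM in wild-type library 1. The heat shock genes Hspa1a and Hspa1b are near-identical copies whose reads cannot be told apart. They measured 22.0 ± 36.1 against 3.71 ± 1.93 FPKM and 26.5 ± 44.5 against 2.76 ± 2.11 FPKM, with 63.6 and 77.9 FPKM in that library. Otud1 measured 64.3 ± 95.7 against 9.65 ± 3.72 FPKM, with 175 FPKM there. S100a8 measured 2.76 ± 2.99 against 52.9 ± 89.7 FPKM, with 156 FPKM in knockout library 3. S100a9 measured 2.54 ± 3.36 against 50.4 ± 84.4 FPKM, with 148 FPKM in that library. The pseudokinase gene Trib3 measured 0.482 ± 0.239 against 3.14 ± 2.02 FPKM (limma adjusted p = 0.0562), and its libraries did not overlap between the genotypes, where chance gives 10%.

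**Figure D2:**
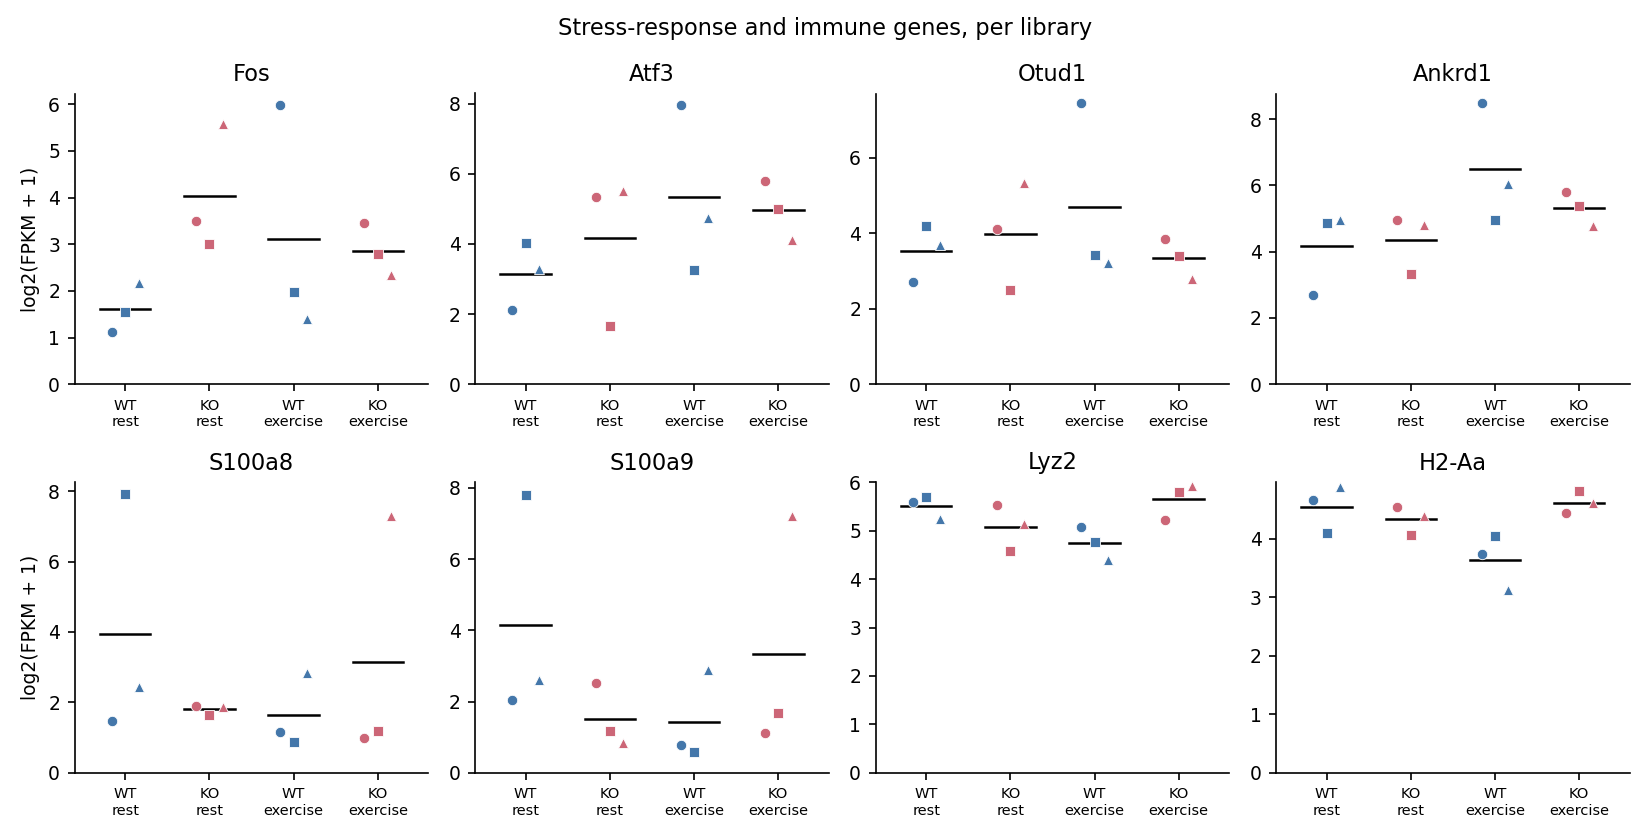
Fos, Atf3, Otud1, Ankrd1, S100a8, S100a9, Lyz2 and H2-Aa as log2(FPKM + 1) in each library at rest and after exercise, wild type blue and knockout red; circles, squares and triangles are replicates 1, 2 and 3, and bars are means of the log values. Otud1 reached 175 FPKM in exercised wild-type library 1, and S100a8 reached 239.5 FPKM in resting wild-type library 2.

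After exercise the authors called 865 of 9037 tested genes, 421 higher and 444 lower in the knockout (q at or under 0.05 in the authors' deposited table). The libraries of the genotypes did not overlap for 82.4% of the called genes and 20.1% of the others, where chance gives 10%. limma called 337 genes, 143 higher and 194 lower. Both tests called 310 genes, 126 higher and 184 lower. The limma count was 103, 79 and 71 without wild-type library 1, 2 and 3. It was 75, 70 and 106 without knockout library 1, 2 and 3, and 40 genes passed in every such fit.

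The unfolded protein and integrated stress response was higher in the exercised knockout. In it 7 of 14 tested members were called higher, 0 lower and 7 neither (11 higher and 0 lower adjusted over the list alone), and 3 passed both tests. The list passed its test (cameraPR adjusted p = 5.55e-18, adjusted p = 0.225 with an estimated correlation), and fry gave an adjusted p of 0.00691. With Mthfd2 and Psat1, Atf5 rose from 8.89 ± 1.54 to 38.4 ± 2.40 FPKM (limma adjusted p = 0.00116) and passed every fit with 1 library left out. Chac1, which degrades glutathione, measured 15.9 ± 6.46 against 35.5 ± 9.47 FPKM (limma adjusted p = 0.0955). The knockout libraries had list medians of 0.83, 0.48 and 0.54 on the log2 scale. Over the group means the list had a median of 0.64, and the immune cell markers had 0.83.

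Fatty acid and triglyceride synthesis was higher after exercise. In this list 7 of 17 tested members were called higher, 1 lower and 9 neither (11 higher and 1 lower adjusted over the list alone, cameraPR adjusted p = 0.00235, adjusted p = 0.225 with an estimated correlation). fry gave an adjusted p of 0.0214, and limma called 0 of the members (10 at an unadjusted p under 0.05). Dgat2 measured 13.8 ± 2.08 against 26.3 ± 6.48 FPKM (limma adjusted p = 0.0624). Thrsp measured 11.4 ± 0.808 against 21.8 ± 6.48 FPKM (limma adjusted p = 0.0705). Acaca, which starts fatty acid synthesis, measured 3.56 ± 0.954 against 5.82 ± 0.363 FPKM (limma adjusted p = 0.102).

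Immune cell markers were higher in the exercised knockout. Here 8 of 13 tested members were called higher, 0 lower and 5 neither (12 higher and 0 lower adjusted over the list alone, cameraPR adjusted p = 2.52e-27, adjusted p = 0.84 with an estimated correlation). Cd68 passed both tests. The class II gene H2-Aa measured 11.9 ± 3.93 against 23.6 ± 3.19 FPKM (limma adjusted p = 0.0636), and its partner Cd74 measured 21.1 ± 7.57 against 36.0 ± 9.15 FPKM. The macrophage receptor Csf1r measured 2.39 ± 0.236 against 4.24 ± 1.26 FPKM. The lysozyme gene Lyz2, a near-identical copy of Lyz1, measured 26.3 ± 6.22 against 50.3 ± 12.3 FPKM (limma adjusted p = 0.0752). The knockout libraries had list medians of 0.48, 0.74 and 1.17, the last in library 3, where S100a8 and S100a9 were high. Without wild-type library 2 limma gave an adjusted p of 0.109 for Cd68.

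Heat shock and immediate early genes were lower in the authors' table after exercise, and both lists moved with wild-type library 1. In the heat shock list 1 of 16 tested members were called higher, 7 lower and 8 neither (1 higher and 8 lower adjusted over the list alone, cameraPR adjusted p = 7.88e-10, adjusted p = 0.895 with an estimated correlation). Its median was 0.89, -0.48 and -0.29 in wild-type libraries 1, 2 and 3. Without library 1 the direction turned to up (cameraPR adjusted p = 0.0113). In the immediate early list 0 of 20 tested members were called higher, 7 lower and 13 neither (0 higher and 7 lower adjusted over the list alone, cameraPR adjusted p = 1.2e-05, adjusted p = 0.84 with an estimated correlation). Its medians were 0.60, -0.24 and -0.35 in the same libraries, and it was not called without library 1 (cameraPR adjusted p = 0.0694). limma called 0 members of either list (2 of the heat shock and 2 of the immediate early list at an unadjusted p under 0.05). Hspb1 measured 283 ± 269 against 110.2 ± 29.7 FPKM, and Dnaja1 measured 27.9 ± 19.6 against 14.2 ± 3.46 FPKM. Fos measured 22.3 ± 34.7 against 6.65 ± 3.01 FPKM, Atf3 95 ± 135 against 33.9 ± 19.4 FPKM and Klf10 12.4 ± 3.96 against 7.68 ± 1.90 FPKM. Hspb7 measured 122 ± 36.5 against 311 ± 136 FPKM (limma adjusted p = 0.0743).

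Denervation, junction and regeneration genes were lower after exercise. In this list 1 of 12 tested members were called higher, 5 lower and 6 neither (1 higher and 6 lower adjusted over the list alone, cameraPR adjusted p = 2.12e-05, adjusted p = 0.84 with an estimated correlation), and 3 passed both tests. Actc1 fell as above, and Chrnb1 fell from 15.9 ± 0.921 to 7.81 ± 1.42 FPKM. Dach2, a transcriptional regulator, fell from 4.21 ± 0.412 to 2.29 ± 0.140 FPKM. Ankrd1 measured 150.4 ± 179 against 40.7 ± 14.5 FPKM, with 357 FPKM in wild-type library 1. Fast fibre genes had 1 higher and 2 lower of 14 (1 and 2 adjusted over the list alone, cameraPR adjusted p = 0.531). Myl1 fell from 15311 ± 580.5 to 7903 ± 547 FPKM, and the myosin-binding protein Mybpc2 fell from 1456 ± 188 to 839 ± 79.5 FPKM. Slow fibre genes had 1 higher and 2 lower of 10 (1 and 3 adjusted over the list alone, cameraPR adjusted p = 0.0548), and the calcium store protein Casq2 fell from 27.3 ± 2.45 to 14.0 ± 2.76 FPKM. The slow list passed without wild-type library 2 (cameraPR adjusted p = 0.0385), wild-type library 3 (0.000584) or knockout library 1 (0.000217). limma fitted without knockout library 2 gave an adjusted p of 0.0961 for Actc1 and 0.0669 for Chrnb1. Leaving out wild-type library 1 gave a limma adjusted p of 0.126 for Dach2. Without wild-type library 2 limma gave an adjusted p of 0.105 for Mybpc2 and 0.0886 for Casq2. limma fitted without wild-type library 3 gave an adjusted p of 0.0556 for Myl1.

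Metabolic lists that missed the threshold after exercise held single genes past both tests. Glycolysis and glycogen had 2 higher and 1 lower of 24 (4 and 1 adjusted over the list alone, cameraPR adjusted p = 0.746). Fbp2 fell from 38.4 ± 1.5 to 15.7 ± 1.67 FPKM and passed every fit with 1 library left out. Purine metabolism had 1 higher and 3 lower of 20 (1 and 3 adjusted over the list alone, cameraPR adjusted p = 0.493). The muscle AMP deaminase Ampd1 fell from 541 ± 38.0 to 326 ± 32.9 FPKM, and the nucleotidase Nt5c1a fell from 11 ± 1.43 to 5.02 ± 1.37 FPKM. Amino acid catabolism had 1 higher and 1 lower of 29 (1 and 0 adjusted over the list alone, cameraPR adjusted p = 0.963), and Pcca rose from 10.3 ± 2.12 to 23.4 ± 6.22 FPKM. The tricarboxylic acid cycle list had 1 higher and 1 lower of 28 (1 and 1 adjusted over the list alone, cameraPR adjusted p = 0.746). Idh2 rose from 97.3 ± 15.2 to 164 ± 21.3 FPKM, and Pdk1 fell from 22.3 ± 1.37 to 12.9 ± 1.07 FPKM. Polyamine metabolism had 1 higher and 2 lower of 10 (2 and 3 adjusted over the list alone, cameraPR adjusted p = 0.139). Spermine synthase, Sms, fell from 66.0 ± 5.66 to 36.6 ± 6.18 FPKM, and Smox fell from 99.9 ± 14.8 to 48.3 ± 14.6 FPKM. The polyamine list passed without knockout library 2 (cameraPR adjusted p = 0.0498). Leaving out wild-type library 1 gave a limma adjusted p of 0.0811 for Ampd1. Without knockout library 2 limma gave an adjusted p of 0.097 for Nt5c1a and 0.121 for Smox. limma fitted without wild-type library 2 gave an adjusted p of 0.0961 for Pcca and 0.0792 for Pdk1. Leaving out wild-type library 3 gave a limma adjusted p of 0.106 for Idh2 and 0.0841 for Sms.

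Signalling, atrophy and clock lists after exercise also missed the threshold. Insulin signalling had 3 higher and 2 lower of 16 (5 and 2 adjusted over the list alone, cameraPR adjusted p = 0.424). Irs1, a substrate of the insulin receptor, fell from 27.6 ± 2.45 to 16.8 ± 1.30 FPKM. Grb14 fell from 8.89 ± 2.00 to 3.68 ± 1.14 FPKM, and Tbc1d4 rose from 3.99 ± 1.54 to 9.06 ± 0.948 FPKM. The atrophy list had 4 higher and 3 lower of 19 (6 and 3 adjusted over the list alone, cameraPR adjusted p = 0.0548). Cdkn1a rose from 9.80 ± 6.37 to 40.1 ± 6.50 FPKM, and Ctsl rose from 33.4 ± 2.83 to 60.3 ± 13.3 FPKM. Circadian genes had 2 higher and 1 lower of 18 (2 and 1 adjusted over the list alone, cameraPR adjusted p = 0.746). Exercise-responsive genes had 5 higher and 2 lower of 17 (6 and 2 adjusted over the list alone, cameraPR adjusted p = 0.0548), and the glycolytic regulator Pfkfb3 fell from 6.69 ± 1.5 to 2.83 ± 0.649 FPKM. The exercise-responsive list passed without wild-type library 1 (cameraPR adjusted p = 1.2e-05), knockout library 2 (0.0344) or knockout library 3 (0.00411). The atrophy list passed without wild-type library 1 (cameraPR adjusted p = 0.00933) or knockout library 2 (0.0498). Without wild-type library 1 limma gave an adjusted p of 0.0869 for Irs1. limma fitted without wild-type library 2 gave an adjusted p of 0.13 for Grb14, 0.0898 for Cdkn1a, 0.125 for Ctsl and 0.116 for Pfkfb3. Leaving out knockout library 2 gave a limma adjusted p of 0.126 for Tbc1d4.

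The remaining lists gave smaller counts after exercise. Fatty acid uptake and oxidation had 5 higher and 1 lower of 29 (10 and 1 adjusted over the list alone, cameraPR adjusted p = 0.11), with the acyl-CoA synthetase Acsl1 at 144 ± 24.1 against 237 ± 52.1 FPKM. Oxidant defence had 4 higher and 1 lower of 16 (4 and 1 adjusted over the list alone, cameraPR adjusted p = 0.221), with Cat at 54.3 ± 13.1 against 80.6 ± 14.1 FPKM. Oxidative phosphorylation had 0 higher and 2 lower of 71 (0 and 1 adjusted over the list alone, cameraPR adjusted p = 0.11), with Ndufb2 at 324 ± 57.4 against 228 ± 28.1 FPKM. This list did pass, as lower, in camera on library values at the preset correlation (adjusted p = 0.00203), but not with an estimated correlation (camera adjusted p = 0.84). Sterol synthesis had 2 higher and 0 lower of 8 (2 and 0 adjusted over the list alone, cameraPR adjusted p = 0.746) and a median of -0.13, although it was tested as up. The corepressor complex had 1 higher and 1 lower of 5 (2 and 1 adjusted over the list alone, cameraPR adjusted p = 0.424), with Tbl1xr1 at 13.2 ± 2.49 against 19.6 ± 0.713 FPKM. Its median was 0.19 and its mean -0.21, and it was tested as down. The member called lower was Hdac3 itself, the targeted gene, whose own fall lowered this mean. Other histone deacetylases had 0 higher and 1 lower of 8 (0 and 1 adjusted over the list alone, cameraPR adjusted p = 0.881), with Hdac2 at 26.4 ± 4.38 against 17.7 ± 2.53 FPKM. Fatty acid oxidation passed without wild-type library 1 (cameraPR adjusted p = 0.0113) or knockout library 2 (0.0278). Oxidative phosphorylation passed without knockout library 3 (cameraPR adjusted p = 0.0185), and oxidant defence without wild-type library 1 (0.0113).

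Markers of cell types other than immune cells held few calls after exercise. Fibroblast markers had 0 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.493), with Dcn at 199 ± 19.7 against 241 ± 73.8 FPKM. Adipocyte markers had 0 higher and 0 lower of 7 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.746), with Fabp4 at 430.1 ± 143 against 453 ± 167 FPKM. Endothelial markers had 0 higher and 0 lower of 10 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.676), with Cdh5 at 15.1 ± 3.27 against 12.3 ± 3.31 FPKM. Smooth muscle and pericyte markers had 0 higher and 0 lower of 5 (0 and 0 adjusted over the list alone, cameraPR adjusted p = 0.302), with Rgs5 at 179 ± 6.92 against 134 ± 13.8 FPKM. Blood markers had 0 higher and 0 lower of 3 (0 and 0 adjusted over the list alone), with Hbb-b1 at 117 ± 70.6 against 135 ± 73.2 FPKM. Schwann cell markers had 0 higher and 0 lower of 4 (0 and 0 adjusted over the list alone), and satellite cell markers had 0 higher and 2 lower of 3 (0 and 2 adjusted over the list alone). cameraPR called 6 of 27 lists, camera on library values with the preset correlation 4, and fry 2. With an estimated correlation camera called 0 (2 at an unadjusted p under 0.05). Without knockout library 2 cameraPR called 10.

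**Figure D3:**
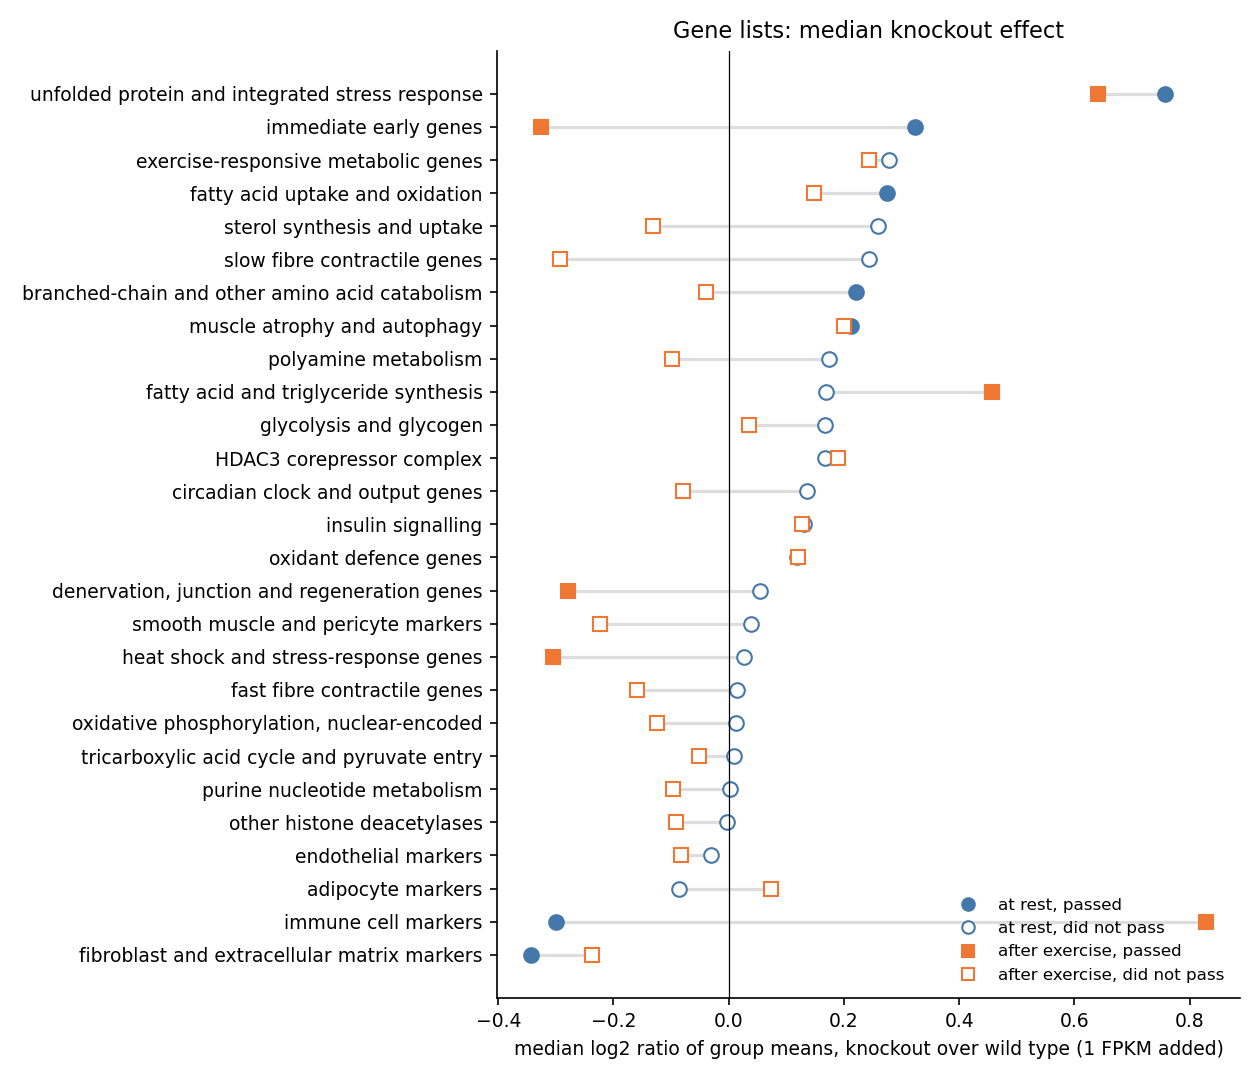
Median log2 ratio of knockout over wild type, with 1 FPKM added to both means, for each gene list at rest (circles) and after exercise (squares); filled symbols passed cameraPR at an adjusted p of 0.05. The integrated stress response list lies at 0.76 at rest and 0.64 after exercise, and immune cell markers at -0.30 and 0.83.

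Levels of exercise-linked genes were set side by side across the resting and exercised tables without a test, because the tables were made separately. Pdk4, an inhibitor of pyruvate dehydrogenase, stood at 149 ± 65.5 FPKM at rest and 635 ± 525 FPKM after exercise in wild type, and at 95.3 ± 29.7 and 653 ± 296 FPKM in knockout. The coactivator Ppargc1a stood at 11.8 ± 2.66 FPKM at rest and 33.4 ± 27.1 FPKM after exercise in wild type, and at 15.0 ± 2.86 and 39.8 ± 19.5 FPKM in knockout. The uncoupling protein Ucp3 stood at 46.9 ± 16.5 FPKM at rest and 119 ± 42.2 FPKM after exercise in wild type, and at 30.5 ± 8.45 and 133 ± 15.1 FPKM in knockout. Foxo1 stood at 4.49 ± 1.78 FPKM at rest and 14.5 ± 2.07 FPKM after exercise in wild type, and at 7.14 ± 2.91 and 18.5 ± 0.908 FPKM in knockout. The metallothionein Mt2 stood at 3.50 ± 1.73 FPKM at rest and 52.9 ± 25.5 FPKM after exercise in wild type, and at 8.72 ± 3.20 and 121 ± 114 FPKM in knockout. Fos stood at 2.20 ± 1.17 FPKM at rest and 22.3 ± 34.7 FPKM after exercise in wild type, and at 21.3 ± 21.9 and 6.65 ± 3.01 FPKM in knockout. Of 17 members of the exercise-responsive list, 13 had a higher mean in wild type after running and 4 a lower mean. Pfkfb3 stood at 13.3 ± 4.33 FPKM at rest and 6.69 ± 1.5 FPKM after exercise in wild type, and at 5.01 ± 3.95 and 2.83 ± 0.649 FPKM in knockout. The growth factor Vegfa stood at 73.6 ± 21.3 FPKM at rest and 67.1 ± 12.1 FPKM after exercise in wild type, and at 93.7 ± 30.5 and 102 ± 14.4 FPKM in knockout. Irs2 stood at 3.65 ± 2.54 FPKM at rest and 2.94 ± 1.21 FPKM after exercise in wild type, and at 3.49 ± 1.51 and 3.84 ± 1.94 FPKM in knockout. Fndc5 stood at 40.9 ± 6.64 FPKM at rest and 39.6 ± 5.51 FPKM after exercise in wild type, and at 46.5 ± 6.75 and 44.6 ± 3.53 FPKM in knockout.

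The knockout effects at rest and after exercise often had the same direction. Both tables called 228 genes higher in the knockout, where independent lists would share 25 of the 8854 genes tested in both (Fisher's exact test, two-sided, odds ratio 32.7, p = 3.7e-183). Both called 231 lower, where independent lists would share 20.6 (Fisher's exact test, two-sided, odds ratio 49.3, p = 1.3e-212). Mthfd2, Slc7a5, Mybph, Tlcd2 and Srrm4os led the genes higher in both, and Gamt, Hdac3 and Actr3b fell in both. Actc1 and Dkk3, called lower in both, passed limma in 1 table each. Dkk3 measured 3.6 ± 1.96 against 0.805 ± 0.211 FPKM after exercise (limma adjusted p = 0.0699). limma called 76 genes higher and 77 lower in both tables, against 4.3 and 3.3 for independent lists. Of 427 genes that passed limma at rest, 418 had the same sign after exercise, and of 329 that passed after exercise, 322 had the same sign at rest. Across 8849 genes the log2 ratios correlated with a Pearson r of 0.526 and a Spearman rho of 0.547, where genes are not independent replicates. Without the called genes the values were 0.275 and 0.416. The tables shared no library.

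**Figure D4:**
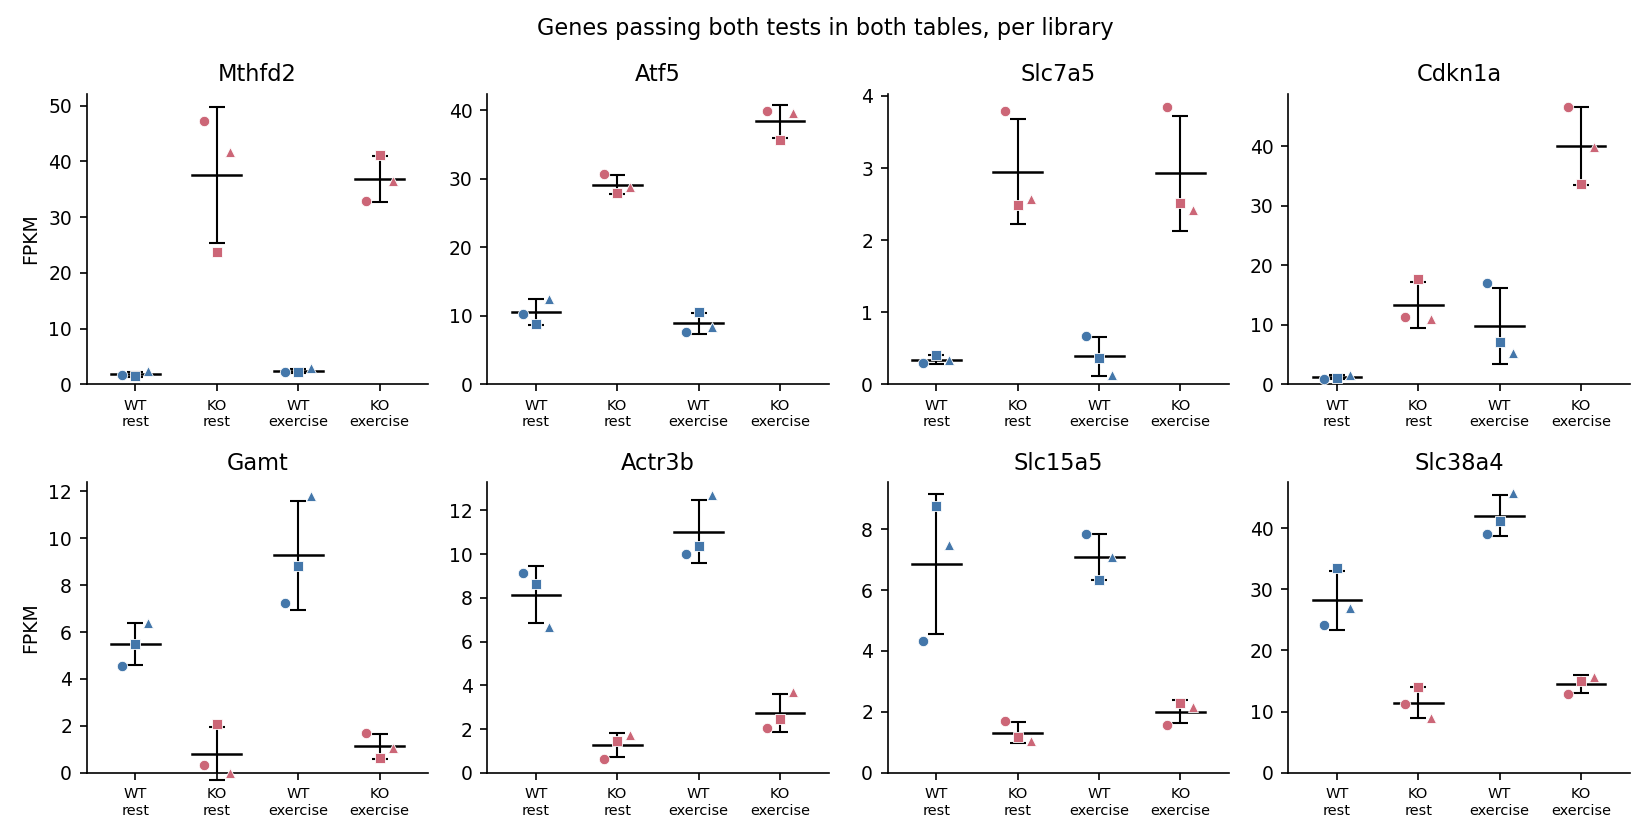
Mthfd2, Atf5, Slc7a5, Cdkn1a, Gamt, Actr3b, Slc15a5 and Slc38a4 in FPKM in each library at rest and after exercise, wild type blue and knockout red; circles, squares and triangles are replicates 1, 2 and 3, bars are means and error bars are SDs (n = 3). Mthfd2 lies at 37.5 and 36.9 FPKM in knockout and at 1.80 and 2.39 FPKM in wild type.

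How many knockout effects differed between rest and exercise depended on the test. The limma interaction contrast over the 12 libraries called 0 of 8854 genes, with 433 at an unadjusted p under 0.05 (4.89%) and a lowest adjusted p of 0.779. A second test, with standard errors implied by the deposited p in place of the planned statistic, called 42 genes, Fos, Atf3 and Cish among them. For genes at the floor of the deposited p, these errors followed from that floor and the ratio of means. Without exercised wild-type library 3 the interaction called 1 gene. The smallest unadjusted p belonged to Rnaset2a, a near-identical copy of Rnaset2b. It measured 0.0703 ± 0.103 against 2.93 ± 0.312 FPKM at rest and 4.24 ± 1.09 against 5.25 ± 1.51 FPKM after exercise (difference of log2 effects -1.63, SE 0.28, limma adjusted p = 0.779). The other named genes had a limma adjusted p of 0.923. The effect after exercise minus that at rest was -0.86 (SE 0.18) for Bcl2l1, -0.48 (SE 0.11) for Zranb2, -0.75 (SE 0.18) for Ssna1 and -0.84 (SE 0.20) for Arrdc4. It was 1.00 (SE 0.19) for Ccr2, 1.2 (SE 0.29) for Lyz1, 0.65 (SE 0.16) for Tmem55b, 0.78 (SE 0.19) for Grn and 0.94 (SE 0.24) for Hipk2. The chemokine receptor Ccr2 measured 2.30 ± 0.374 against 1.80 ± 0.245 FPKM at rest and 1.43 ± 0.253 against 3.11 ± 0.0768 FPKM after exercise. The authors called 12 genes in opposite directions, among them Fos, Atf3, Cish, S100a8 and S100a9. limma passed 0 of the 12 in either table (6 in either table and 0 in both at an unadjusted p under 0.05). Among 902 genes at an unadjusted limma p under 0.05 in both tables, 3 went in opposite directions.

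**Figure D5:**
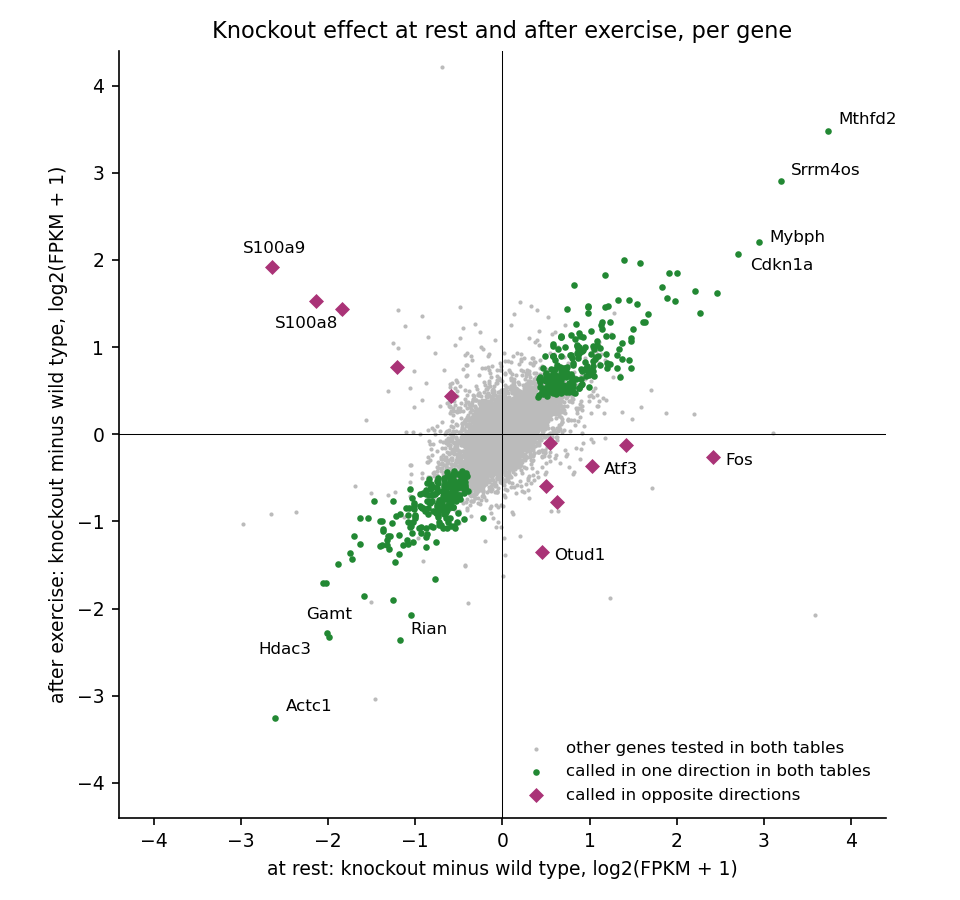
limma log2 difference of knockout minus wild type at rest (x axis) against after exercise (y axis), 1 point per gene tested in both tables; green marks genes called in the same direction in both tables and purple diamonds genes called in opposite directions. The 228 genes higher in both lie in the upper right and the 231 lower in both in the lower left, and 4 genes lie outside the drawn range.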

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

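The test of a difference took standard errors from the deposited p in place of the planned statistic. All tests of explanations here, except those of library scaling for exercised wild-type library 1 and of bone marrow, were chosen only after the result was seen. With standard errors implied by the deposited p, 19 genes named in the lists or across tables had a knockout effect that differed between rest and exercise. The limma interaction contrast gave them adjusted p-values between 0.923 and 0.934. The deposited p stopped at 5e-05, and Cish, Atf3, S100a9 and Fos were among the genes at this floor in both tables. For such genes the implied error followed from the floor and the ratio of means alone. Their adjusted p therefore does not grade the evidence. Wild type against knockout (n = 3), Cish measured 7.28 ± 2.83 against 2.64 ± 1.56 FPKM at rest and 3.56 ± 0.677 against 8.71 ± 8.38 FPKM after exercise (adjusted p = 3.23e-05 from implied errors), with 18.4 FPKM in exercised knockout library 1. Hipk2 measured 9.80 ± 2.53 against 5.93 ± 0.773 FPKM at rest and 7.31 ± 0.446 against 9.42 ± 1.03 FPKM after exercise (adjusted p = 0.00643), and myostatin, Mstn, 28.8 ± 3.85 against 31.9 ± 10.3 FPKM at rest and 40.4 ± 8.62 against 21.8 ± 7.04 FPKM after exercise (adjusted p = 0.0305).

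A first group was high in exercised wild-type library 1, and part of it also in resting knockout library 3. Atf3 (3.23e-05, adjusted p from implied errors), Fos (9.01e-05), Csrnp1 (0.000343), Cyr61 (0.000669), Otud1 (0.000669), Ier5 (0.0121), Dnajb1 (0.0278), Ankrd1 (0.0292) and Btg2 (0.0488) belonged to it. In exercised wild-type library 1 Fos was 62.5 FPKM against 2.94 and 1.64 in the other wild-type libraries, Atf3 250.5 against 8.57 and 25.9, and Dnajb1 80.9 against 2.62 and 2.84. In resting knockout library 3 Fos was 46.5 FPKM against 10.4 and 7.01 in the other knockout libraries, Otud1 39.3 against 16.4 and 4.62, and Btg2 17.5 against 8.97 and 9.18. The limma effect on Fos was 2.41 at rest and -0.26 after exercise. A second group was of immune cells: S100a9 (3.23e-05), S100a8 (0.00992), Lyz2 (0.00371), H2-Aa (0.0276), Ccr2 (0.0292), Csf1r (0.0458) and Lyz1 (0.0471). Lyz2 measured 44.9 ± 7.09 against 34.0 ± 11.1 FPKM at rest and 26.3 ± 6.22 against 50.3 ± 12.3 FPKM after exercise, H2-Aa 22.9 ± 6.25 against 19.2 ± 3.34 FPKM at rest and 11.9 ± 3.93 against 23.6 ± 3.19 FPKM after exercise and Csf1r 3.56 ± 0.413 against 2.94 ± 0.458 FPKM at rest and 2.39 ± 0.236 against 4.24 ± 1.26 FPKM after exercise.

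For the stress genes, the 14 members of the heat shock and immediate early lists called lower after exercise were taken as the pattern, and 13 of them were highest of the 6 libraries in exercised wild-type library 1, by a median of 2.485 on the log2 scale over the other 2 wild-type libraries. Their median knockout effect was -0.589 with that library and 0.044 without it. These results were partly built in, because the genes were chosen for a higher wild-type mean in the same libraries. Over all tested members the heat shock list had log2 medians of 0.89, -0.48 and -0.29 in exercised wild-type libraries 1, 2 and 3. The immediate early list had 0.60, -0.24 and -0.35, so library 1 also stood out without that choice. A knockout library labelled as wild type is argued against by Hdac3 at 31 FPKM there, library scaling by a median difference of -0.007 over all tested genes, and other cell types by marker lists that rose by at most 0.19 (fibroblast markers). What stays open is a difference of that sample in handling, harvest or running response, which was not tested.

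For the neutrophil genes, all 13 on the marrow list were highest in resting wild-type library 2 and all 13 in exercised knockout library 3, where S100a8 reached 239.5 and 156 FPKM. Bone marrow in those pieces of muscle is a candidate explanation: 89.5% (17 of 19) of the other marrow genes above 0 at rest and 84.2% (16 of 19) after exercise were highest in the same library, and 1 of the 19, Ebf1, averaged 1 FPKM or more in the other 5 libraries of each table. Blood stays open, because the haemoglobin genes rose by 0.418 of the neutrophil rise after exercise and 0.285 at rest while being high in every library (Hbb-b1 128 ± 75.8 FPKM in resting knockout), which can hide a small added share; the bound set for that test was therefore wrong. As a cause of the rise, loss of HDAC3 is argued against at rest, where the rise lay in a wild-type library with Hdac3 at 31 FPKM. A lowering by the knockout stays open there, because 2 of 13 neutrophil genes separated the genotypes and 7 could not, with 0 FPKM in a wild-type library. After exercise, loss of HDAC3 by itself is argued against as the cause of a rise of that size. Knockout libraries 1 and 2, also low in Hdac3, lay below knockout library 3 for all 13 genes. They held S100a8 at 0.991 and 1.26 FPKM and S100a9 at 1.15 and 2.19 FPKM. A smaller effect of HDAC3 loss stays open after exercise. There 15.4% of the neutrophil genes (2 of 13) separated the genotypes and 9 could not, with 0 FPKM in a knockout library.

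The integrated stress response list was higher in the knockout by a median of 0.757 at rest and 0.641 after exercise, while the median over all tested genes was 0.0063 at rest and -0.0006 after exercise, which argues against library scaling. Other cell types are argued against at rest, where the highest marker list median was 0.038 (smooth muscle and pericyte markers). After exercise they stay open, because immune cell markers had a median of 0.828 and were highest in knockout library 3, whereas the stress list was highest in knockout library 1. Acute stress of handling or running stays open too, because the immediate early list had a median of 0.323 at rest (8 of 18 called higher), although pooled with the heat shock list it was 0.167 at rest and -0.327 after exercise (0.141 without exercised wild-type library 1). A lasting response to the loss of HDAC3 remains open beside these.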

How the results depend on the processing

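Tests between libraries, list tests on library values and the interaction contrast were chosen only after the data were seen. The other alternatives were planned, with the deposited p standing in for the absent statistic in the test of a difference. Against 998 genes called at rest and 865 after exercise, a q at or under 0.01 gave 605 and 492, an absolute log2 fold change of at least 1 gave 238 and 250, limma gave 434 and 337, and both tests together gave 393 and 310; the first pair follow from stricter rules, and for limma the cause was not tested. The counts stayed within 1.5 times with a q at or under 0.10 (1328 and 1128), recentring (996 and 869), repeated adjustment (998 and 868), removal of overlapping genes (905 and 785) and libraries that do not overlap (826 and 713, with 10% of genes by chance). limma called 247 and 109 genes with no filter on low values, where many more genes were tested, and between 20 and 292 at rest and 70 and 106 after exercise with 1 library left out, where fewer samples remained. Other limma settings gave 379 to 461 genes at rest and 281 to 385 after exercise. With the replicate number as a block limma called 52 and 170. Same-numbered deviations correlated at 0.00, 0.05 and 0.05 at rest and 0.03, -0.33 and -0.18 after exercise. Differently numbered ones lay between -0.14 and 0.36 after exercise. These values gave no sign of pairing by number, but 3 libraries per group cannot exclude it or a shared batch.

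The correlation of the knockout effects fell from 0.526 to 0.275 (Pearson) and from 0.547 to 0.416 (rank) without Hdac3 and the called genes, which removes the largest effects, and lay between 0.458 and 0.581 (rank 0.489 and 0.558) with 1 library left out. Genes called in one direction in both tables numbered 459, 277 at a q of 0.01 or less and 153 with limma. Against 7 lists at rest and 6 after exercise, camera with an estimated correlation called 0 and 0, fry 0 and 2, random lists matched on expression 11 and 12 (median outside the central 95%), and camera on library values at the preset correlation 4 at rest, while leaving out 1 library gave 4 to 8 and 7 to 10; the cause was not tested. Heat shock genes after exercise turned from down to up without wild-type library 1 (cameraPR adjusted p = 0.0113), the library in which they were high. Leaving out 1 library gave them an adjusted p between 7.46e-17 (without wild-type library 2) and 0.0113. Genes whose effect differed numbered 0 with limma, 42 with standard errors implied by the deposited p, and 0 to 1 with 1 library left out. The cause of this gap was not tested. Among named genes, leaving out 1 library kept the side of the threshold in 1089 cases, ended a call in 304 and made one in 17; other settings did so in 1523, 108 and 14. A normal p from the deposited statistic was not run because the tables hold none, and a minimum of 1 FPKM removed no tested gene. Read depth was unknown, so its limit on low genes cannot be given.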

Other observations

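The genes in this part were chosen after their values were seen, as were all tests here except those of chromosome neighbours. Some large differences lay outside the fixed lists. Mib1, a ubiquitin ligase of the Notch pathway, rose from 19 ± 1.90 to 74.2 ± 4.45 FPKM at rest (limma adjusted p = 0.000718) and from 18.4 ± 4.75 to 67.9 ± 8.61 FPKM after exercise (0.00466). Gstm2, a glutathione transferase with close relatives in the genome, rose from 38.0 ± 9.22 to 154 ± 17.0 FPKM at rest (limma adjusted p = 0.00487) and from 38.7 ± 1.24 to 144 ± 27.0 FPKM after exercise (0.00154). Hat1, a histone acetyltransferase, rose from 10.9 ± 1.04 to 23.9 ± 0.432 FPKM at rest (limma adjusted p = 0.00554) and from 12.9 ± 1.44 to 24.7 ± 2.60 FPKM after exercise (0.0175). The lysosomal protease Lgmn rose from 15.7 ± 2.05 to 38.1 ± 2.41 FPKM at rest (limma adjusted p = 0.00554) and from 12.9 ± 1.49 to 32.8 ± 2.22 FPKM after exercise (0.0035). Ccdc136 rose from 2.49 ± 0.496 to 11.5 ± 2.41 FPKM at rest (limma adjusted p = 0.00554) and from 2.84 ± 0.178 to 11.4 ± 1.26 FPKM after exercise (0.00154). Cd55, which restrains complement, fell from 29.9 ± 3.33 to 7.50 ± 1.99 FPKM at rest (limma adjusted p = 0.00554) and from 26.5 ± 2.21 to 8.81 ± 0.485 FPKM after exercise (0.00154). Setd8, a histone methyltransferase, fell from 42.0 ± 2.20 to 16.7 ± 1.83 FPKM at rest (limma adjusted p = 0.00487) and from 39.1 ± 0.546 to 16.9 ± 0.569 FPKM after exercise (0.00205). All 7 passed limma in every fit with 1 library left out, except Hat1 after exercise (adjusted p = 0.0656 without wild-type library 2).

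Of 33 imprinted genes listed after values were seen, 27 were tested at rest and 26 after exercise. At rest the authors called 2 higher and 6 lower (1 and 3 by both tests), and after exercise 5 lower (4 by both tests). Both tests passed 14.8% of them at rest against 4.27% of all tested genes, and 15.4% after exercise against 3.43%, without a test of the shares. Snrpn, Snurf and Snhg14 entered these counts separately. The amino acid transporter Slc38a4 fell from 28.2 ± 4.78 to 11.4 ± 2.51 FPKM at rest (limma adjusted p = 0.0162) and from 42.0 ± 3.36 to 14.5 ± 1.43 FPKM after exercise (0.00165). Snrpn, which overlaps Snurf and Snhg14 so that their reads cannot be told apart, fell from 9.08 ± 1.59 to 2.87 ± 0.576 FPKM at rest (limma adjusted p = 0.0107) and from 9.57 ± 1.45 to 3.40 ± 0.904 FPKM after exercise (0.0146). H19 rose from 82.2 ± 11 to 166 ± 33.3 FPKM at rest (limma adjusted p = 0.0241) and measured 109 ± 37.4 against 136 ± 14.4 FPKM after exercise (limma adjusted p = 0.433). Without wild-type library 2 limma gave an adjusted p of 0.0746 for Slc38a4, 0.0567 for Snrpn and 0.103 for H19 at rest, and 0.0574 for Snrpn after exercise. Slc38a4 passed every such fit after exercise.

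A change of the chromosome around the targeted gene was tested as an explanation of the shared calls. Of the 50 tested genes nearest to Hdac3, 2 (4.0%) were called in one direction in both tables, against 5.18% of 8803 other genes (Fisher's exact test, two-sided, p = 1.0). This argues against an excess of shared calls around Hdac3. In any case 50 genes could not hold most of the 459 shared calls. At rest the neighbours Pfdn1, Hbegf, Fgf1, Sh3rf2, Lars, Eif3j2 and Myot were called higher, and the other neighbours were not called. A local change at rest alone was not tested. For Mib1, 0 of its 10 nearest tested genes were called higher in both of the authors' tables, which argues against a change of the region around that gene.

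Other splits of the libraries were refitted. With 3 libraries per genotype only 10 splits per table exist, too few for a share under 0.05: limma called 434 genes at rest and 337 after exercise with the real split and at most 2 with another split in each table, the real split being the 1 with as many. For lists, cameraPR called 7 at rest, as many as in 3 of the 10 splits (highest other 8), and 6 after exercise, as many as in 8 of the 10 (highest other 11). For the correlation of the effects, the real split was the 1 of 100 with as high a Pearson r (0.606 on the limma effects, highest other 0.408). This argues against chance but cannot exclude it, because the 100 reuse the 10 splits of each table and are not independent. For genes whose effect differed by the limma interaction contrast, the real count was 0, so all 100 splits reached it by construction (highest other 5) and nothing about chance follows.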
